A study of Homo sapiens with 6 samples.

How the data were processed

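RNA of 6 samples of BT474 cells, 3 infected with a control hairpin lentivirus (shCon) and 3 with a MEL-18 hairpin lentivirus (shMEL), was measured on 1-colour Illumina bead arrays. Groups and sample numbers were taken from the sample titles. Per the labels' protocols, total RNA was isolated with Trizol, checked on a Bioanalyzer and turned into biotinylated cRNA with the Illumina TotalPrep kit. Per the submitters' processing notes, the data passed through GenomeStudio, with no version given, and its background and normalization settings are not given in the sources used here. The deposited values are probe intensities on a linear scale. They range from -19.1 to 17184, and 25.8% of the values on each array are below 0, so a background had been subtracted. The sorted values of the 6 arrays differ by at most 0.48, so the authors had made the intensity distributions of the arrays equal, as quantile normalization does. Both statements are read from the values.

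The deposited intensities were used without further normalization. An offset of 20, the smallest round number that makes all values positive, was added before log2. The offset had not been fixed before the data were examined, unlike the test, the lists, the filter and the naming rule. Fold changes are therefore on the log2(intensity + 20) scale and understate the change of dim probes. The deposited table used here gives no detection p-value, so a background level was set on each array as the 95th percentile of 457 probes of olfactory receptor genes, which epithelial cells rarely express. It lay between an intensity of 10.3 and 13.7, with 37.3% to 41.4% of probes above it. Probes above it on at least 3 of the 6 arrays were tested, and others are called not above background.

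Probes were named through the platform annotation, whose Entrez identifiers were checked against a RefSeq gene table. Of 47216 probes, 30106 had 1 gene symbol, 8 had several and 17102 are unnamed here, and 0 symbols had to be updated. A probe with several symbols was not named. A gene is represented by its tested probe with the highest mean over the 6 arrays, and probes of a gene that disagree are given where the gene is discussed. Listed genes that matched no named probe were not analysed here. Probe positions were not used, since no genome build is given in the sources used here. CKMT1A and CKMT1B are near-identical, and their probes may not tell them apart.

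Each probe was tested for shMEL against shCon with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the trend and robust options and no covariate. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 18348 probes tested, at a threshold of 0.05. The residual degrees of freedom were 4 and the prior degrees of freedom 12.4. A fixed set of 33 gene lists was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. For each list the single-gene calls were also counted adjusted over the list alone. A set test needed at least 3 tested members. The lists overlap in places: CDKN1A is both a p53 target and a cyclin-dependent kinase inhibitor, and ERBB2 is in the receptor and the amplicon list. The study may have chosen ErbB and sheddase genes on these same samples, so these lists are not independent evidence of a direction.

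The genes named in the text were fixed by a rule: PCGF2, all members of the ErbB receptor, ErbB ligand and ADAM lists, the 10 highest and 10 lowest fold changes among genes past the threshold whose arrays do not overlap between groups and that lie above background on all 3 arrays of the brighter group, and, of each other list, up to 4 called members or else the 2 with the smallest p. Genes named beyond this rule are said to have been chosen after their values were seen.

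The code was tested on 20 simulated data sets of 18348 probes with the spread of the real arrays and 200 changed probes. It recovered 27.7% of probes changed 1.3-fold, 83% of those changed 1.6-fold, 98.5% of those changed 2-fold and 99.7% of those changed 3-fold, and 7.71% of the calls were false. A list shifted by 0.3 on the log2 scale was called in 20 of 20 runs, with 0.15 other lists called per run. Simulated probes were drawn independently, with the spread estimated by eBayes, so their genes were not correlated. The list counts therefore do not show how often lists of correlated genes are called falsely. The shift of 0.3 was also larger than the mean change of any list in the real data. No 2 arrays were duplicates: the correlation of log2 values between arrays ran from 0.987 to 0.993, and at most 35 of 47216 values were identical.

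Alternatives fixed before the data were examined were other background filters, other normalizations of the log2 values, an offset of 50, eBayes without its options, array weights, a replicate block, each array left out in turn, stricter thresholds, the other set tests and the mean of a gene's probes. Fits with 1 option of eBayes, an offset of 50 with plain eBayes, and lists without their called members were added after seeing the data. Figures were drawn with matplotlib 3.10.9.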

Results

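Gene expression was profiled in BT474, a human breast ductal carcinoma cell line that carries an amplified ERBB2 (HER2) gene. The cells had been stably infected with a lentivirus carrying either a short hairpin RNA against MEL-18 (shMEL) or a control hairpin (shCon). MEL-18 is the protein of the gene PCGF2, a Polycomb group RING finger protein of the repressive complex PRC1. Each group had 3 samples, each hybridised to its own 1-colour Illumina bead array, and the table held 47216 probes on 6 arrays. Of these, 18348 probes (38.9%) lay above background on at least 3 arrays and were tested. Arrays have no sequencing depth, so the number of arrays limits the precision: the median standard error of a log2 fold change was 0.126. The labels do not say that the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The series asks how MEL-18 bears on the phosphorylation of the ErbB receptors, the growth factor receptor family of EGFR and HER2. The arrays measure the RNA of these genes and not phosphorylation.

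The targeted gene was measured first. The 1 probe of PCGF2 fell from a mean intensity of 1818 ± 132 (SD, n = 3) in shCon to 998 ± 44.3 (SD, n = 3) in shMEL, so that 54.9% of the control signal remained. The shCon arrays read 1964, 1708 and 1782, and the shMEL arrays 982, 963 and 1048. The log2 fold change was -0.85 (SE 0.0868, limma adjusted p = 0.000539), the smallest p-value of all probes tested. The labels and the target gene thus went the same way on all 6 arrays.

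Over the whole array, 35 probes rose and 49 fell in shMEL at an adjusted p under 0.05, which is 0.458% of the probes tested. Of the called probes, 73 had a gene name and 11 are unnamed here. By the brightest tested probe of each gene, 61 of 10676 named genes passed, 30 higher and 31 lower. NBL1 (-0.66, adjusted p = 0.0294), MPST (-0.65, 0.0121), NUPR1 (-0.59, 0.00985) and AZIN1 (0.59, 0.0423) passed only by a dimmer probe. They are not among the 61 and were named after their values were seen. The changes of the 61 genes were at least 0.37 in size on the log2(intensity + 20) scale. On that scale, which understates the change of dim probes, the largest were 1.82-fold higher and 1.90-fold lower. For all 61 genes the 3 shMEL arrays lay outside the range of the 3 shCon arrays. Such a separation held for 19.1% of the genes tested, against 10% by chance.

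Of the 10 genes with the largest rise, LCN2, the iron-siderophore binding protein lipocalin 2, rose by 0.86 on the log2 scale (SE 0.123, adjusted p = 0.00328), from an intensity of 72.0 ± 11.8 to 147 ± 13.1 (SD, n = 3 per group). TFF1, a trefoil peptide induced by oestrogen, had the highest signal of the 10 and rose from 2701 ± 201 to 4432 ± 270, a log2 fold change of 0.71 (adjusted p = 0.00165). The protease inhibitor SERPINA3 rose by 0.70 (519 ± 14.5 to 854 ± 38.4, adjusted p = 0.00193) and the prolactin-induced protein PIP by 0.72 (adjusted p = 0.0101). BCL2, the inhibitor of apoptosis, rose by 0.77 (121 ± 13.5 to 220 ± 25.9, adjusted p = 0.00458, with another probe at 0.60 and 0.0569), and ANXA1, a phospholipid-binding annexin, by 0.75 (adjusted p = 0.00985). The proton pump subunit ATP6V1B1 rose by 0.69 (adjusted p = 0.00193) and SYNPO2L by 0.70 (adjusted p = 0.00735). CDH2 (N-cadherin), at 0.76 with an adjusted p of 0.0166, and ZNF735, at 0.85 with an adjusted p of 0.0309, were dim, with shCon means of 26.7 and 31.0.

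The 10 genes with the largest fall, PCGF2 among them, included 2 neighbours of ERBB2 on 17q12. PPP1R1B, which encodes the phosphatase inhibitor DARPP-32, fell by 0.92 (SE 0.153, adjusted p = 0.0101), from a low intensity of 58.1 ± 14.6 to 20.8 ± 2.97. PNMT, the enzyme that makes adrenaline from noradrenaline, fell by 0.75 (357 ± 19.6 to 204 ± 17.9, adjusted p = 0.00193). PTMS (parathymosin) fell by 0.88 (341 ± 47.4 to 175 ± 2.90, adjusted p = 0.00193), and the fatty acid desaturase gene FADS2 fell by 0.80 (adjusted p = 0.0121). The imprinted, retrotransposon-derived gene PEG10 fell by 0.79 (adjusted p = 0.00735, with another probe at -0.42 and 0.359), the uroplakin gene UPK1A by 0.79 (adjusted p = 0.00193) and CERCAM by 0.76 (adjusted p = 0.00373). CFDP1 fell by 0.75 (adjusted p = 0.00193), and SCGN, which encodes the calcium-binding protein secretagogin, fell by 0.73 (adjusted p = 0.0105).

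**Figure D1:**
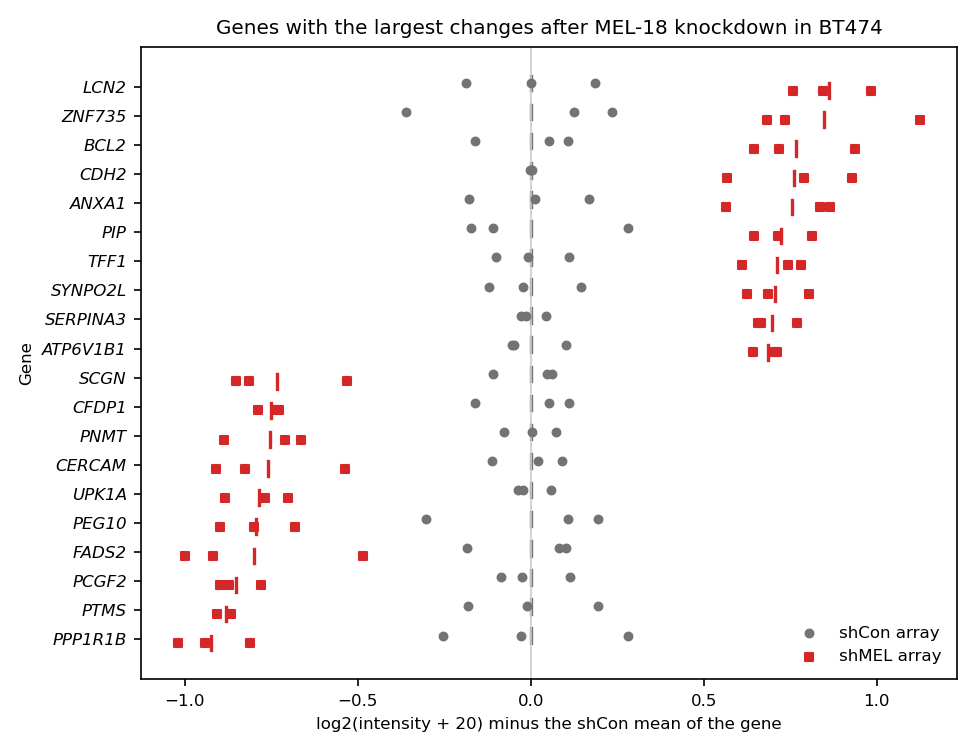
Per-array values of the 10 genes with the largest rise and the 10 with the largest fall. The horizontal axis gives log2(intensity + 20) minus the shCon mean of the gene, each row is a gene, grey circles are the 3 shCon arrays, red squares the 3 shMEL arrays and short vertical lines the group means. In all 20 rows the shMEL arrays lie on one side of the shCon arrays, from a mean of 0.86 for LCN2 to -0.92 for PPP1R1B.

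The number of calls depended on the variance model and on single arrays. With limma's eBayes without its trend and robust options no probe passed (0 higher and 0 lower, with 2024 probes at an unadjusted p under 0.05 and PCGF2 at an adjusted p of 0.0767), against 2246 at that unadjusted p in the main test. The counts were 9 higher and 18 lower without shCon 1, 22 and 51 without shCon 2, 290 and 246 without shCon 3, 9 and 23 without shMEL 1, 10 and 18 without shMEL 2, and 6 and 13 without shMEL 3. Of the 24 genes past the threshold that the naming rule selected besides PCGF2, 9 passed in each of the 6 fits without 1 array: LCN2, TFF1, SERPINA3, ATP6V1B1, PTMS, UPK1A, CERCAM, PNMT and CFDP1. PCGF2 passed in each of them too, and the other 15 lost the call in 1 to 5 of these fits. Calls were also gained: PTPN11, HOXB13, MCM7, TOP2A, HEY2, HIF1A, EBP, SDHC and RPS2, described below as not past the threshold, passed without shCon 3. HEY2 also passed with array weights (adjusted p = 0.0443).

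The ErbB receptor genes were compared because the series is about them. ERBB2 was bright and had a mean intensity of 8591 ± 164 in shCon and 7386 ± 332 in shMEL (SD, n = 3 per group). Its log2 fold change was -0.22 (SE 0.0698, adjusted p = 0.223), and that of ERBB3 was -0.25 (SE 0.104, adjusted p = 0.331). EGFR was dim, with a log2 fold change of -0.14 (adjusted p = 0.702), and ERBB4 was not above background on any array. A dimmer probe of EGFR went the other way (0.09, adjusted p = 0.867), and a dimmer one of ERBB3 showed no change (-0.00086, adjusted p = 0.999). No receptor gene passed over all probes, while 2 of the 3 tested, ERBB2 and ERBB3, were lower when adjusted over the list alone. As a set the 3 genes were lower than other genes (mean -0.20, camera adjusted p = 0.0374 over 33 lists), but not with an estimated correlation (adjusted p = 0.303). The set call was also lost with the mean of a gene's probes (mean -0.12, adjusted p = 0.187), with the replicate number as a block (mean -0.20, adjusted p = 0.0512), and without shCon 2 (0.0914), shCon 3 (0.0859), shMEL 1 (0.058) or shMEL 2 (0.157).

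The ligands of these receptors that matched a named probe were near or below background, other than TGFA. Of 11 ligand genes listed, 9 were matched to named probes and 4 were tested. AREG and EPGN matched no named probe, so their level is not known here. TGFA, which encodes the EGFR ligand TGF-alpha, had a log2 fold change of 0.37 (SE 0.141, adjusted p = 0.307), from 41.2 ± 8.81 to 58.6 ± 7.82, and its other probe gave 0.40 (adjusted p = 0.255). The log2 fold changes of EGF, BTC and NRG3 were 0.20, 0.10 and -0.03, with adjusted p-values of 0.705, 0.863 and 0.968. HBEGF, EREG, NRG1, NRG2 and NRG4 were not above background on enough arrays to be tested. No ligand passed over all probes or adjusted over the list alone, and the set did not pass (mean 0.16, adjusted p = 0.316).

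The ADAM metalloproteases that release ErbB ligands and receptor domains from the cell surface were also compared. Of 9 genes, 5 were tested, and none passed over all probes or adjusted over the list alone. The brightest probe of ADAM10 had a log2 fold change of 0.16 (95% confidence interval -0.13 to 0.44, adjusted p = 0.672). A dimmer one, above background on 1 shCon array and on all 3 shMEL arrays, had 0.51 (0.12 to 0.91, adjusted p = 0.274). The 3 probes of ADAM17 went both ways: the brightest had a log2 fold change of -0.04 (95% confidence interval -0.29 to 0.21, adjusted p = 0.926). The dimmer ones of ADAM17 had 0.38 (0.05 to 0.71, adjusted p = 0.328) and -0.22 (-0.62 to 0.19, adjusted p = 0.683). The log2 fold changes of ADAM9, ADAM12 and ADAM15 were -0.08, 0.32 and -0.16, with adjusted p-values of 0.903, 0.516 and 0.51. The other probes of ADAM15 gave -0.13, -0.09 and 0.11 (adjusted p = 0.607, 0.812 and 0.791). ADAM8, ADAM19, ADAM28 and ADAM33 were not above background on enough arrays. The set had a mean of 0.04 and a median of -0.04, which differ in sign, and did not pass (adjusted p = 0.931).

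**Figure D2:**
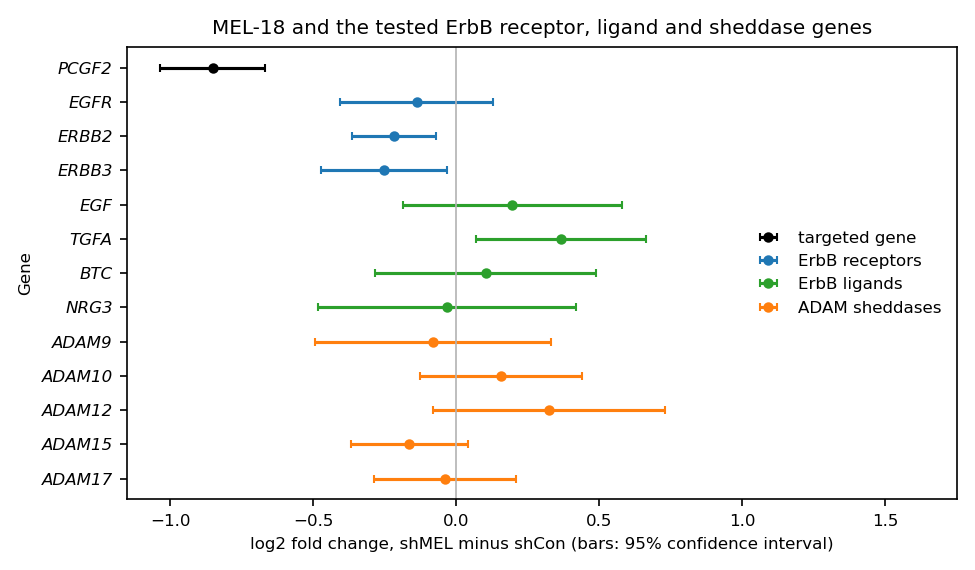
Log2 fold changes, shMEL minus shCon, of PCGF2 and of the tested ErbB receptor, ligand and ADAM sheddase genes, each by its brightest probe. Points are estimates from 3 arrays per group, bars are 95% confidence intervals and colours mark the gene list. PCGF2 lies at -0.85, ERBB2 at -0.22 and TGFA at 0.37, and the drawn intervals of all ADAM genes include 0. Of the dimmer probes, which are not drawn, an ADAM10 probe (0.51) and an ADAM17 probe (0.38) had intervals above 0. Another ADAM17 probe (-0.22) had an interval that includes 0.

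No group of genes around this pathway passed as a set with all 6 arrays. Among 12 tested regulators of the sheddases, TIMP1, an inhibitor of metalloproteases, had a log2 fold change of -0.40 (adjusted p = 0.263) and RHBDF2, a rhomboid protein that escorts ADAM17, had 0.35 (adjusted p = 0.227). The other probes of RHBDF2 gave 0.15 and -0.01 (adjusted p = 0.636 and 0.985). That set did not pass with all 6 arrays (mean -0.13, adjusted p = 0.126) but passed without shCon 2 (mean -0.18, adjusted p = 0.0444). Nor did 19 ErbB adaptors and kinases pass (mean 0.06, adjusted p = 0.333), whose members with the smallest p were ERRFI1 at 0.29 and PTPN11 at 0.37 (adjusted p = 0.285 and 0.358). Neither list had a call over all probes or adjusted over the list alone. Among 20 feedback and immediate early genes of the MAPK pathway, EGR1 fell by 0.57 (adjusted p = 0.0423), and adjusted over the list alone 1 gene was higher (DUSP6) and 3 were lower (EGR1, FOS and IER3), with no shift of the set (mean -0.04, adjusted p = 0.482). Of 13 FOXO target genes, the insulin receptor substrate IRS1 rose by 0.62 (adjusted p = 0.0306), and adjusted over the list alone IRS1 and BCL6 were higher and GADD45A was lower (set mean 0.06, adjusted p = 0.482). EGR1 did not pass with the replicate number as a block (adjusted p = 0.0982), with the trend option of eBayes alone (0.0552) or at an offset of 50 with plain eBayes (0.0636), nor without shCon 1, shCon 2, shMEL 2 or shMEL 3. IRS1 passed only without shCon 3 among the fits without 1 array.

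No other Polycomb gene passed singly. None of 19 tested PRC1 components passed, with PCGF6 at -0.15 and RING1 at -0.10 (adjusted p = 0.629 and 0.686), and the set had a mean of -0.02 (adjusted p = 0.631). The 2 dimmer probes of PCGF6 went the other way (0.15 and 0.29, adjusted p = 0.702 and 0.454). None of 11 PRC2 components passed, with SUZ12 at 0.23 and RBBP7 at 0.22 (adjusted p = 0.32 and 0.327), and the set mean was 0.08 (adjusted p = 0.249). HOX genes, the classic targets of Polycomb repression, were lower as a set: of 13 tested, 10 had a negative fold change (mean -0.15, adjusted p = 0.0157, and adjusted p = 0.241 with an estimated correlation). No HOX gene passed over all probes, but HOXB13 (-0.56, adjusted p = 0.0616) and HOXC9 (-0.36, adjusted p = 0.224) were lower adjusted over the list alone. HOXB13 passed in the fit of 1 mean per named gene, where its fold change is the same (adjusted p = 0.0261), and without shCon 3 (adjusted p = 0.0482). The HOX call was lost without shCon 3 (adjusted p = 0.0967) or shMEL 2 (0.0609) and with no background filter (0.0697, mean -0.07). Of 40 developmental transcription factors known as Polycomb targets, 13 were tested and none passed, with SOX9 at 0.17 and IRX5 at -0.14 (adjusted p = 0.539 and 0.566). Their mean was -0.02 and their median 0.01, which differ in sign (adjusted p = 0.798).

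Luminal and oestrogen-response genes were higher as a set in shMEL. Of 22 tested, 15 had a positive fold change (mean 0.14, adjusted p = 0.0157, and adjusted p = 0.241 with an estimated correlation). BCL2, TFF1 and STC2, the secreted glycoprotein stanniocalcin 2 (log2 fold change 0.50, adjusted p = 0.0294), passed over all probes. Adjusted over the list alone, 7 were higher and 2 were lower, the luminal keratins KRT8 (-0.25) and KRT19 (-0.23). The progesterone receptor gene PGR was among the 7, at 0.38. Without BCL2, TFF1 and STC2 the set did not pass (mean 0.06, adjusted p = 0.377), nor did the full set without shCon 3 (0.0887) or shMEL 2 (0.0504). Leaving out members called in these same data favours the loss of a set, here and in the lists below. Such a loss does not show that the other members were unchanged.

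NF-kB target and cytokine genes were also higher as a set. Of 15 tested, 11 had a positive fold change (mean 0.20, adjusted p = 0.0157, and adjusted p = 0.421 with an estimated correlation). LCN2 passed over all probes, and adjusted over the list alone LCN2, RELB (0.57), CXCL8 (0.44), CXCL10 (0.44) and CCL20 (0.44) were higher. The set did not pass without LCN2 (mean 0.15, adjusted p = 0.0555) or without shMEL 1 (0.058). Of 15 tested interferon-response genes none passed (mean -0.07, adjusted p = 0.249), with OAS3 at -0.35 and MX2 at -0.19 (adjusted p = 0.274 and 0.471), and of 13 antigen presentation genes none passed (mean -0.09, adjusted p = 0.221), with HLA-F at -0.48 and HLA-B at -0.29 (adjusted p = 0.223 and 0.307).

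Targets of the tumour suppressor p53 were lower as a set. Of 17 tested, 14 had a negative fold change (mean -0.19, adjusted p = 0.0017, and adjusted p = 0.241 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, fell by 0.66 (585 ± 108 to 358 ± 12.1, SE 0.114, adjusted p = 0.0121), and adjusted over the list alone the apoptosis gene BAX (-0.55) was lower too. Without CDKN1A the other members were still lower as a set at the preset correlation (mean -0.16, adjusted p = 0.0157). CDKN1A itself passed without shCon 2 or shCon 3 but not without any of the other 4 arrays. It was the only called member among 5 tested cyclin-dependent kinase inhibitors, over all probes and adjusted over the list alone, and that set did not pass (mean -0.16, adjusted p = 0.273).

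Genes of the G1/S transition and DNA replication were slightly lower as a set. Of 22 tested, 14 had a negative fold change (mean -0.11, adjusted p = 0.0271, and adjusted p = 0.241 with an estimated correlation). None passed over all probes or adjusted over the list alone, and the helicase subunit MCM7 and E2F2 had log2 fold changes of -0.28 and -0.29 (adjusted p = 0.179 and 0.207). The set call was lost without shCon 2 (adjusted p = 0.108), shMEL 1 (0.058) or shMEL 2 (0.0504). Of 27 G2/M and mitosis genes none passed and the set did not pass with all 6 arrays (mean 0.06, adjusted p = 0.156) but passed without shCon 2 (mean 0.09, adjusted p = 0.0428), with TOP2A at 0.41 and UBE2C at 0.21 (adjusted p = 0.223 and 0.29).

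The genes of the 17q12 amplicon around ERBB2 were lower as a set. Of 19 tested, 13 had a negative fold change (mean -0.15, adjusted p = 0.0157, and adjusted p = 0.241 with an estimated correlation). PPP1R1B and PNMT passed over all probes, and ERBB2 was lower too adjusted over the list alone. Without PPP1R1B and PNMT the set did not pass (mean -0.07, adjusted p = 0.239), nor did the full set without shMEL 2 (adjusted p = 0.0759). Of 10 tested genes in the stretch of 17q12 next to PCGF2, PCGF2 alone passed, over all probes and adjusted over the list alone. That set did not pass with PCGF2 (mean -0.12, adjusted p = 0.126) or without it (mean -0.04, adjusted p = 0.482).

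Epithelial state genes showed single changes, and none of these lists passed as a set. Of 5 tested mesenchymal genes CDH2 rose, and adjusted over the list alone CDH2 was higher and TWIST1 (-0.34) and TGFBI (-0.38) were lower (set mean -0.02, adjusted p = 0.482). None of 6 basal and myoepithelial genes passed (mean -0.13, adjusted p = 0.249), with CDH3 at -0.31 and ITGA6 at -0.28 (adjusted p = 0.283 and 0.591). None of 18 epithelial adhesion genes passed (mean -0.02, adjusted p = 0.631), with LLGL2 at -0.32 and DSP at 0.17 (adjusted p = 0.346 and 0.491) and a dimmer probe of LLGL2 at 0.04 (adjusted p = 0.956). Of 10 stem cell genes, the hyaluronan receptor CD44 rose by 0.66 (adjusted p = 0.0293), and adjusted over the list alone CD44 was higher and ALDH1A1 (-0.51) was lower (set mean 0.05, adjusted p = 0.482). The other probes of CD44 gave 0.36 and 0.18 (adjusted p = 0.459 and 0.683), and its call was lost with the mean of its probes (0.40, adjusted p = 0.145). CD44 passed only without shCon 3 among the fits without 1 array, and CDH2 only without shCon 3 or shMEL 2. Of 14 Notch pathway genes none passed over all probes, while HEY2 (0.43, adjusted p = 0.102) was higher and NOTCH3 (-0.31, adjusted p = 0.221) was lower adjusted over the list alone (set mean -0.05, adjusted p = 0.377). None of 16 Wnt pathway genes passed (mean -0.06, adjusted p = 0.377), with FZD7 at 0.32 and CTNNB1 at -0.24 (adjusted p = 0.374 and 0.417).

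No metabolic, stress response or ribosomal list passed as a set. Among 13 fatty acid synthesis genes FADS2 fell, and adjusted over the list alone FADS2 was lower while ELOVL5 (0.44), ME1 (0.35) and ACSL1 (0.32) were higher. The mean of that set was 0.00076 and its median -0.04, which differ in sign (adjusted p = 0.854). None of 17 cholesterol synthesis genes passed (mean -0.08, adjusted p = 0.156), with EBP at -0.33 and SC5D at 0.31 (adjusted p = 0.183 and 0.252). None of 25 hypoxia and glycolysis genes passed (mean 0.06, adjusted p = 0.323), with NDRG1 at -0.29 and HIF1A at 0.44 (adjusted p = 0.297 and 0.305). None of 21 genes of the unfolded protein and integrated stress responses passed (mean -0.03, adjusted p = 0.482), with PDIA4 at -0.25 and PHGDH at -0.17 (adjusted p = 0.414 and 0.415). None of 29 oxidative phosphorylation genes passed (mean 0.04, adjusted p = 0.381), with ATP5F1C at 0.22 and SDHC at -0.28 (adjusted p = 0.28 and 0.299) and a dimmer probe of SDHC at 0.17 (adjusted p = 0.545). Of 31 ribosomal protein genes none passed over all probes, and RPS2 (-0.30) and RPS9 (-0.33) were lower adjusted over the list alone (set mean 0.01, adjusted p = 0.787). No member of any other list passed adjusted over the list alone.

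In all, 7 of 33 lists passed camera's test with its preset correlation of 0.01, 2 higher and 5 lower, and 0 passed with an estimated correlation (lowest adjusted p = 0.241, with 5 lists at an unadjusted p under 0.05). The estimated correlations of the ErbB receptor (-0.15), HOX (-0.0124), G1/S (-0.0179), luminal (-0.00768) and amplicon (0.00563) lists lay below the preset value. Those of the p53 (0.022) and NF-kB (0.14) lists lay above it. A higher correlation thus does not account for the lost calls of the lists below the preset value. The fry test, which asks only whether the members move one way, passed 9 lists, 6 of them among the 7. It did not pass the NF-kB list (adjusted p = 0.114), and it also passed the PRC2 components (0.047), the basal genes (0.0421) and the neighbours of PCGF2 (0.047). Genes named here because they passed only adjusted over a list alone were chosen after their values were seen.

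**Figure D3:**
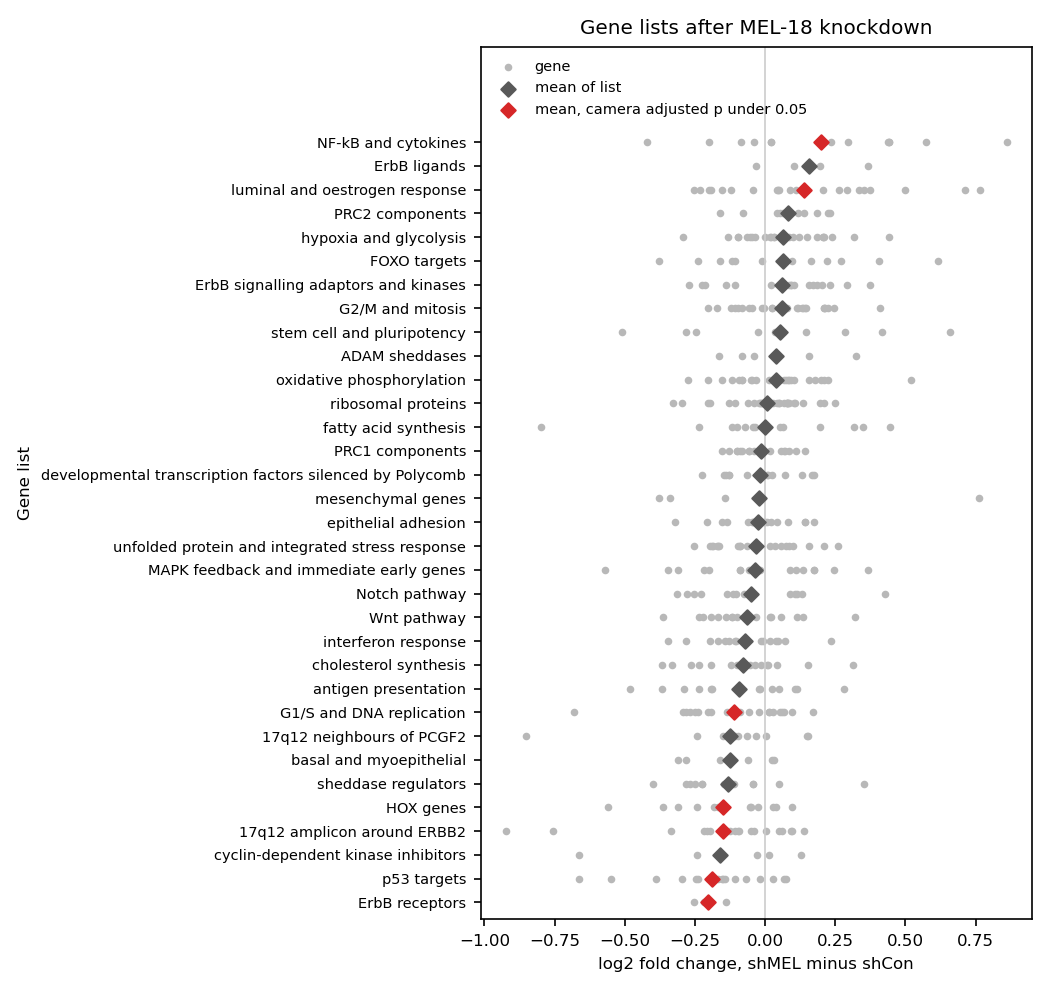
Log2 fold changes, shMEL minus shCon, of the tested members of the 33 gene lists. Each row is a list, grey points are genes, diamonds are the mean of the list, and red diamonds mark the 7 lists with a camera adjusted p under 0.05 at the preset correlation. The means lie between -0.20 for the ErbB receptors and 0.20 for the NF-kB and cytokine genes, while single genes such as LCN2 reach 0.86.

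Markers of cell types other than tumour epithelium were mostly below background. Above it were 1 of 10 fibroblast markers (COL1A1, log2 fold change -0.20), 1 of 9 leukocyte markers (CD68, -0.15) and 2 of 7 endothelial markers (VWF, -0.20, and ESAM, 0.17). None of these passed the test, and their adjusted p-values were 0.606, 0.588, 0.535 and 0.743.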

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

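The fits with 1 option of eBayes, the offset of 50 with plain eBayes and the lists without called members were chosen after seeing the data. All 84 called probes kept their sign in every alternative that tested them, but this was largely fixed in advance. Their arrays do not overlap between the groups, so leaving out 1 array could not turn a sign. The eBayes options, the filters and the replicate block do not alter the fold change of a probe. Some results that never passed changed sign. With the mean of a gene's probes ADAM17 was at 0.042 and PCGF6 at 0.0958, and the means of the stem cell, fatty acid and ribosomal lists were -0.00946, -0.0157 and -0.00528. The fatty acid mean was also negative with no background filter (-0.0277) and cyclic loess (-0.00129), and that of the developmental transcription factors positive with no filter (0.00192) and with a mean above the median (0.0350). Without 1 array the means ran from -0.0363 to 0.0469 for the fatty acid list, from -0.0384 to 0.00418 for the developmental transcription factors, and from -0.00221 to 0.0870 for the stem cell list. They ran from -0.00400 to 0.0233 for the ribosomal list and from -0.000794 to 0.0958 for the ADAM sheddases. Of single genes, BTC ran from -0.0372 to 0.201, NRG3 from -0.208 to 0.13, ADAM9 from -0.277 to 0.0603 and ADAM17 from -0.123 to 0.0497. Scaling moved the median of all probes by less than 0.003, and the background filters, normalizations and the offset of 50 gave 32 to 36 probes higher and 46 to 49 lower, against 35 and 49. As the deposited arrays already had equal distributions, median centring and quantile normalization could change little. They do not test the normalization of the authors, which could not be varied. Array weights gave 50 and 61. eBayes without the trend and robust options gave 0 and 0, and with the robust option alone 0 and 0, with PCGF2 still at -0.85 but at adjusted p-values of 0.0767 and 0.0787; 2024 and 2006 probes had an unadjusted p under 0.05. The trend option alone gave 30 and 44, and plain eBayes with an offset of 50 gave 29 and 39, and the cause of the loss was not tested. A fold of at least 1.5 left 23 and 32, and limma's treat against a fold of 1.2 left 0 and 1 (35 and 49 by the main test, 2246 at an unadjusted p under 0.05). Without 1 array the counts ran from 6 to 290 higher and from 13 to 246 lower, the highest without shCon 3 and the lowest without shMEL 3, and the cause was not tested. The log2 values of shCon 3 correlated more with shMEL 1 (0.9916) than with shCon 1 (0.9881) or shCon 2 (0.99). With shMEL 2 and shMEL 3 they correlated at 0.9897 and 0.9884. The highest correlation of any pair also lay between the groups (shCon 2 and shMEL 2, 0.9934). Lists past the threshold numbered 2 to 7 without 1 array (4 without shCon 3, 4 without shMEL 1 and 2 without shMEL 2), 0 with an estimated correlation and 9 with fry, against 7. The sheddase regulators (-0.18, adjusted p = 0.0444) and G2/M genes (0.09, adjusted p = 0.0428) passed without shCon 2. The ErbB receptor mean of -0.20 lost its call with an estimated correlation (-0.20, adjusted p = 0.303) and with the mean of a gene's probes (-0.12, 0.187), and ran from -0.17 to -0.22 without 1 array (adjusted p = 0.0197 to 0.157). The same sample numbers occur in both groups, but the sample titles do not say that they pair the samples. Deviations from the group mean of same-numbered arrays correlated at -0.095, 0.19 and -0.0398. Not every array correlated best with its own number (shCon 3 and shMEL 1, 0.249). With so few arrays, centred within each group, these values cannot exclude that some numbers share a batch. A fit with the replicate number as a block gave 42 higher and 52 lower, with 76 of the 84 calls in both, and the ErbB receptor mean was -0.20 (adjusted p = 0.0512). Over named genes and all alternatives, 1284 values kept their sign and side of the threshold, 102 lost a call, 11 gained one and 9 changed sign; for the lists these numbers were 651, 27, 5 and 15. Signal over background limits the dim genes: the ErbB ligands that matched a named probe, but for TGFA, lay near or below it.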

Other observations

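The genes in the next paragraph, the splits of the samples, both copy number tests of the 17q12 genes and the histone test were chosen after the results were seen, and the lists for the other tests were drawn up after ID1, ID3, LCN2, S100A8 and S100A9 had been seen to change. PNMT, PPP1R1B, H2AC6, H4C8, ID1, ID3, LCN2, S100A8 and S100A9 were picked because they passed. A gap between them and the uncalled rest of their group was thus favoured by the choice.

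Several called genes lay outside the lists and the naming rule. Among the highest signals, TCN1, which encodes the vitamin B12 carrier haptocorrin, rose from an intensity of 9492 ± 2138 to 14031 ± 239 (SD, n = 3 per group), a log2 fold change of 0.59 (limma adjusted p = 0.0423). The matrix protein gene MGP rose by 0.47 (adjusted p = 0.0133), with a further probe at 0.60 (adjusted p = 0.00193), and MUCL1, a small mucin-like breast protein, by 0.37 (adjusted p = 0.0351). S100A8 and S100A9, whose proteins form calprotectin, rose by 0.55 and 0.58 (adjusted p = 0.0493 for both). Both probes of DEPTOR, an inhibitor of the mTOR kinase, rose by 0.64 (adjusted p = 0.00396 and 0.0121). ID1 and ID3, which encode inhibitors of basic helix-loop-helix transcription factors, fell by 0.67 and 0.65 (adjusted p = 0.00193 and 0.00458). The growth factor receptor gene FGFR4 fell by 0.47 (adjusted p = 0.0368), the metallothionein gene MT1F by 0.60 (adjusted p = 0.0247), and DEGS1, the desaturase that completes ceramide, by 0.54 (adjusted p = 0.0137). The creatine kinase genes CKMT1A and CKMT1B fell by 0.65 and 0.49 (adjusted p = 0.00857 and 0.0423), but they are near-identical and may be 1 signal.

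The 84 probes past the threshold were set against the other splits of the 6 arrays into 3 and 3. Only 1 of the 10 splits, the real one, gave as many, and the highest of the others gave 2. With 10 splits the share cannot fall under 0.05.

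The 17q12 amplicon genes were lower in shMEL as a set at the preset correlation but not with an estimated one (adjusted p = 0.241), and PNMT and PPP1R1B were the called ones. A lower copy number of the whole amplicon in the shMEL cells was weighed as the cause of the fall of PNMT and PPP1R1B. The other 17 tested members had a median log2 fold change of -0.0918 (SD 0.131), against a mean of -0.84 for these 2 genes. The others thus did not shift by that size. Since PNMT and PPP1R1B were picked as called genes, this gap does not argue against a lower copy number of the amplicon. A small loss across the amplicon stays open, since the other members tended lower without passing (mean -0.07, a camera p of 0.0868, adjusted p = 0.145 over the 5 sets tested in this part), and it cannot be told apart from no change with 17 members. The mean of the full set ran from -0.136 to -0.161 over the 6 fits without 1 array, so no single array makes up the difference. At the preset correlation the highest unadjusted camera p of these fits was 0.0138, but the call adjusted over the lists was lost without shMEL 2 (adjusted p = 0.0759). A regulatory effect of MEL-18 on PNMT and PPP1R1B, an effect of the hairpin on other transcripts and a difference between the infected populations may each account for the fall, and none of these was tested.

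H2AC6 and H4C8, which encode histones of the replication-dependent clusters, rose by 0.65 and 0.58 (adjusted p = 0.0181 and 0.0121). A hypothesis was that the signal of clustered histone genes rose as a group. Of the other 27 tested members, 20 had a positive and 7 a negative fold change and 0 were called, with a median of 0.13 (SD 0.20) and a mean of 0.10 (a camera p of 0.00681, adjusted p = 0.034 over the 5 sets), but the unadjusted p was 0.0826 with an estimated correlation. The group as first defined held 28 genes, with an H1 gene outside the clusters, and gave a p of 0.0269 (adjusted p = 0.0672). It was narrowed after that value was seen. The median of the others lies below the mean of 0.62 for H2AC6 and H4C8 by more than their spread, so the others did not shift by that size. Since H2AC6 and H4C8 were picked as called genes, this gap does not argue against a shift of the group. A smaller shift of the group stays open, and its evidence depends on the preset correlation and on the definition of the group.

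The fall of ID1 and ID3, which are targets of BMP and SMAD signalling, might reflect lower BMP signalling. The other 8 tested target genes showed no shift as a group, with a median of 0.01 (SD 0.129) and a camera p of 0.746 (adjusted p = 0.746). The mean of ID1 and ID3 was -0.66. BMP signalling itself was not measured. The rise of LCN2, S100A8 and S100A9 might be part of a rise of secreted epithelial defence genes. The other 10 tested genes of that kind had a median of 0.19 (SD 0.242), below the mean of 0.66 for these 3 by more than their spread. They did not pass as a set (a camera p of 0.232, adjusted p = 0.29). The others thus did not shift by that size, and a smaller shift of the group stays open. Since the 3 genes were picked as called genes, the gap does not argue against such a shift.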
